A study of Mus musculus with 38 samples.

How the data were processed

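Liver RNA of male mice aged 11 to 12 weeks on a mixed FVB/N and C57Bl/6 background was measured per the labels on Agilent two-colour arrays. RNA was extracted with a Qiagen RNeasy kit and DNase, and 200 ng was labelled with a low input two-colour kit. Each of the 2 dye channels of an array was deposited as a sample of its own, and the values are log2 intensities of single channels, as deposited. The labels give raw files of GenePix format per array, and the submitters' processing notes name R 3.1.0 and limma 3.20.1. Background correction and the normalization within and between arrays are not given in the sources used here. The 38 deposited columns held 45220 features, with values from 5.07 to 16.0 and column medians from 5.72 to 5.78. Correlations between columns ran from 0.9655 to 0.9954, and from 0.9759 to 0.9952 within groups. That the scale is log2 follows from the range of the values and the use of limma, and it was checked against the values. Detection calls were not used here, and signal over background was not available as a number. The labels describe the fasted state both as an overnight fast and as a 24 h fast, and which held was not settled.

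Samples were grouped by the genotype and feeding state in the titles and characteristics, which gave 11 groups of 3 or 4 mice over 37 samples. Each group's mouse numbers differ, so replicates were separate mice. The glucose mice carry higher numbers (659 to 727) than the fasted (486 to 552) and refed mice (467 to 566), and no group separates the glucose treatment from that difference. Other compared groups are apart in number too: refed IR/FoxO1 floxed mice (467 to 473) from fasted ones (516 to 533) and from refed IR floxed mice (506 to 566), refed LIRKO mice (553 to 565) from fasted ones (505 to 550) and from refed LIRFKO mice (468 to 524), and glucose LIRFKO mice (725 to 727) from glucose LIRKO mice (667 to 697). 1 sample, IRF.KO_GTT_724, has labels that conflict on its treatment and was left out of every comparison. The samples lay on 20 arrays of 5 slides, read from the raw file names in the labels. 5 slides with the order of arrays on each were taken as the technical batches.

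Of the features, 33026 paired with 1 gene, 0 with several and 12194 with none. Genes numbered 22485, of which 16347 had 1 probe and 6138 had several, and the probe with the highest mean represented each gene. Features without a gene name were fitted apart and are given as counts. Nothing was filtered on level, and no values were centred or scaled anew.

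limma 3.58.1 with statmod 1.5.0 in R 4.3.3 fitted 1 mean per group over the 37 samples, with dye as a fixed term and array as a random block (consensus correlation 0.358, residual degrees of freedom 25, prior degrees of freedom 1.97). 24 comparisons were tested with moderated statistics, and p was adjusted by Benjamini and Hochberg over all genes within each comparison, with 0.05 as the threshold. Differences between responses, and between knockout effects with and without FoxO1, were tested as contrasts of the same fit. Errors of changes are SE from that fit, and errors of group means are SD. The number of mice per group limits the precision.

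28 pathway lists and 11 cell type marker lists were fixed before the data were examined, as were the comparisons, the named genes and the alternatives, except where the text says otherwise. Lists with 5 or more measured genes, 37 in number, were tested with cameraPR at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated per list. Of 233 list calls at the preset correlation, 44 held with the estimated one. Members past the threshold were counted over all genes and adjusted over the list alone. Lists whose call did not pass in a comparison are not described there, except cholesterol synthesis on refeeding in LIRKO. Mean shifts within a slide are differences between group means of the mean over the measured members. Among the alternatives, shifts within slides are medians over the members of differences averaged over slides.

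Genes were named by a fixed rule. It took the 5 largest rises and the 5 largest falls among genes with an adjusted p under 0.05, no overlap between the samples compared, and a mean above the median of all genes. It added up to 4 members of smallest p from each list and 14 key genes of insulin action, of which 12 were measured here. For differences of responses the limit on overlap was dropped, and predicted gene models were passed over. A value above 15.8 counted as the top of the range, and with a whole group there a difference of group means is a bound. Pck1, Mt2, Creld2, Aass and Igfbp2 had single libraries there in some groups.

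Refeeding and glucose responses of a genotype share its fasted mice, so overlaps were set beside 20 simulations of unchanged groups on the same fasted mice and beside the number from independent lists, and the covariance of both responses beside its simulated mean. Alternatives changed 1 choice each: no array block, no dye term, slide as a fixed block, quantile normalization, each channel centred on its median, the lowest 40% of genes left out, the mean of all probes, trend and robust eBayes, the compared groups alone, both floxed groups as control, and each mouse left out in turn. After the data were seen, fits without IRF.fl_Fast_523 and fits without IR.fl_Fast_486, IR.fl_GTT_659 and IRF.KO_Refed_478 were added. In simulated data with 22485 genes, 92.5% of planted 1 log2 changes were recovered in refed LIRKO against IR floxed (15 of 190 calls false). In fasted LIRFKO against IR/FoxO1 floxed it was 86.6% (8 of 169). The real controls there hold IRF.fl_Fast_523 and Foxo1 did not pass, so 86.6% does not describe that comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.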

Results

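Liver RNA was measured on Agilent two-colour arrays from mice with the insulin receptor deleted in hepatocytes by albumin-Cre (LIRKO), mice with both the insulin receptor and the transcription factor FoxO1 deleted there (LIRFKO), and floxed controls (IR floxed and IR/FoxO1 floxed). Mice were fasted, fasted and then refed for 6 h, or fasted and then given glucose for 60 min. The 37 libraries that the labels place in a group are separate mice. IR floxed mice were 4 fasted, 4 refed and 3 given glucose. LIRKO mice were 3, 4 and 3, LIRFKO mice were 3, 4 and 3, and IR/FoxO1 floxed mice were 3 fasted and 3 refed, with none given glucose. They lay on 20 arrays, most of which carried 2 libraries. Single libraries are named by their titles, in which IR.fl and IRF.fl are the floxed groups, IR.KO and IRF.KO are LIRKO and LIRFKO, and GTT is glucose. Column medians lay between 5.72 and 5.78 log2, and 22485 genes were tested. Changes are differences of log2 values ± SE from limma with an adjusted p, and a gene changed where its adjusted p over all genes was under 0.05. Calls lost with 1 mouse left out are named with the highest adjusted p so reached. Insulin lowers FoxO1 activity in liver, so the comparisons ask which feeding and knockout effects need the receptor, and which of those need FoxO1.

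Insr and Foxo1, the deleted genes, were read first. Insr averaged 8.57 ± 0.372 log2 (SD, n = 4) in fasted IR floxed mice, 7.95 ± 0.191 refed (n = 4) and 8.35 ± 0.376 after glucose (n = 3). In LIRKO it was 6.83 ± 0.549 (n = 3), 6.51 ± 0.162 (n = 4) and 7.21 ± 0.578 (n = 3), where glucose IR.KO_GTT_690 lay at 7.805, above 2 of the 4 refed IR floxed libraries (7.771 and 7.793). In LIRFKO it was 6.61 ± 0.181 (n = 3), 6.15 ± 0.178 (n = 4) and 6.25 ± 0.072 (n = 3). Foxo1 lay at 6.92 ± 0.173, 6.73 ± 0.257 and 6.33 ± 0.231 in the same LIRFKO groups, and at 10.28 ± 0.322, 9.26 ± 0.118 and 9.81 ± 0.23 in LIRKO. In IR floxed mice Foxo1 was 10.35 ± 0.25, 9.62 ± 0.455 and 10.5 ± 0.391, and in refed IR/FoxO1 floxed mice Insr was 7.52 ± 0.19 and Foxo1 9.40 ± 0.241 (n = 3). Fasted IR/FoxO1 floxed mice were uneven, at 7.77 ± 0.756 for Insr and 9.17 ± 2.09 for Foxo1 (n = 3). The library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, held Foxo1 at 6.77 and Insr at 6.90, against 10.57 and 10.17 for Foxo1 in the other mice of that group. It stayed in its labelled group, and counts that used the group are also given without it, while list medians are given with it. Where the probes sit relative to the deleted exons was not known here.

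**Figure D1:**
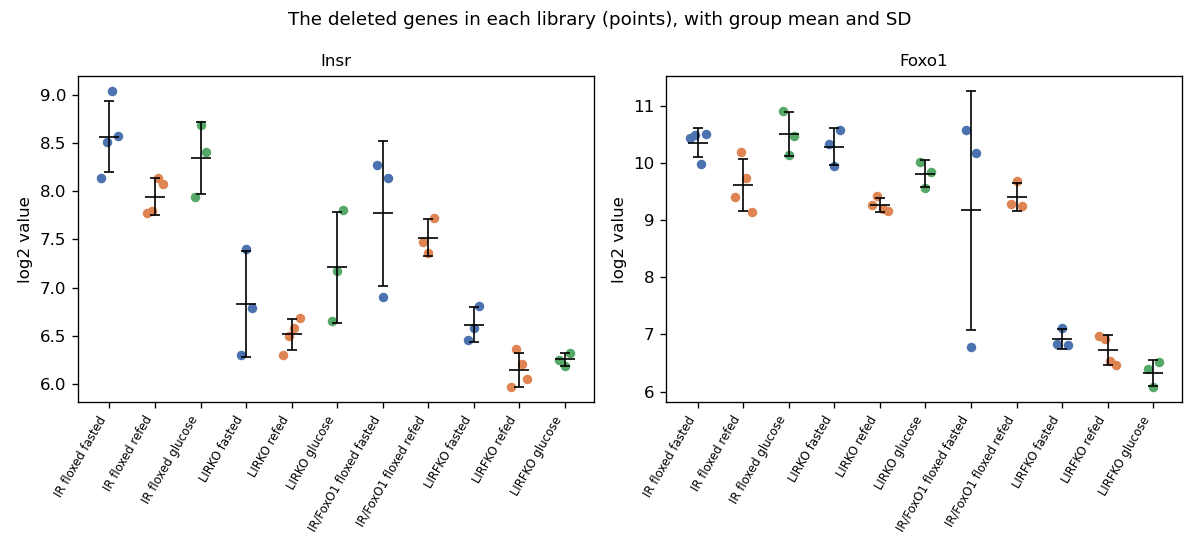
Insr (left) and Foxo1 (right) in each library as log2 values (points; blue fasted, orange refed, green glucose), with group mean and SD as bars. Mean Foxo1 lies between 6.33 and 6.92 in the 3 LIRFKO groups, and 1 fasted IR/FoxO1 floxed library, IRF.fl_Fast_523, is as low at 6.77.

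Refeeding in the floxed controls lowered gluconeogenesis genes and raised chaperone genes of the endoplasmic reticulum. In IR floxed mice (n = 4 and 4) the insulin-repressed Igfbp1 fell by 3.61 ± 0.69 log2 (adjusted p = 0.00295), and the glucose-producing enzyme genes G6pc and Pck1 fell by 2.08 ± 0.42 and dropped by 1.46 ± 0.42 (adjusted p = 0.00461 and 0.0483). Angptl8, a hormone gene induced by feeding, rose by 3.40 ± 0.50 and the lipogenic Thrsp by 2.92 ± 0.76, with smaller rises of Srebf1 (0.79 ± 0.21) and Fasn (0.96 ± 0.27). The metal-binding Mt2 fell by 2.67 ± 0.37 and Ppargc1a fell by 1.83 ± 0.38. Chaperone and unfolded protein response genes of the endoplasmic reticulum moved together: 16 of 19 rose, 0 fell and 3 did not pass over all genes, against 19 and 0 adjusted over the list alone (median 1.13, cameraPR adjusted p = 3.6e-32, adjusted p = 3.6e-04 with an estimated correlation), with Creld2 (2.95 ± 0.47), Pdia6 (1.24 ± 0.19) and Xbp1 (1.09 ± 0.20) among them. Within single slides that list's mean shifted by 1.59 and 1.93. For gluconeogenesis 0 of 11 rose and 5 fell, 0 and 6 adjusted over the list alone (median -0.98, adjusted p = 4.5e-06, adjusted p = 3.6e-04 with an estimated correlation), with mean shifts within slides of -0.995 and -0.673. FoxO1 targets counted 1 of 20 rose and 7 fell, 1 and 11 adjusted over the list alone (median -0.50, adjusted p = 6.9e-08, adjusted p = 3.6e-04 with an estimated correlation). Ribosome biogenesis genes such as Nolc1 (0.78 ± 0.16) and Gnl3 (0.81 ± 0.18) followed the chaperones: 9 of 21 rose and 0 fell, 14 and 0 adjusted over the list alone (median 0.37, adjusted p = 1.4e-11, adjusted p = 0.007 with an estimated correlation). Fatty acid oxidation genes, with Angptl4 (-1.81 ± 0.35) and Cpt1a (-0.94 ± 0.26), counted 0 of 25 rose and 2 fell, 0 and 5 adjusted over the list alone (median -0.45, adjusted p = 1.1e-07, adjusted p = 0.11 with an estimated correlation). In all, 811 genes changed (477 higher, 334 lower), and 720 with slide as a block. Left out in turn, the 8 libraries gave 418 (without IR.fl_Fast_542) to 791 (without IR.fl_Refed_508), and 3 moved the count over 1.5 times. Pck1 (0.156 without IR.fl_Refed_566), Thrsp (0.127 without IR.fl_Refed_506), Srebf1 (0.113 without IR.fl_Refed_508), Fasn (0.134 without IR.fl_Fast_491), Gnl3 (0.0645 without IR.fl_Fast_542) and Cpt1a (0.147 without IR.fl_Refed_566) lost their calls with 1 mouse left out. Without IRF.fl_Fast_523 in any fit the adjusted p of Pck1 was 0.0524.

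In IR/FoxO1 floxed mice (n = 3 and 3) refeeding gave a strong rise of sterol synthesis genes. Mvd rose by 2.84 ± 0.49 log2 (adjusted p = 0.00125), Aacs by 3.32 ± 0.59 and Lss by 2.27 ± 0.41, beside Fasn (1.63 ± 0.31) and Acly (1.18 ± 0.18). Igfbp1 fell by 3.61 ± 0.78 (adjusted p = 0.00787), Pck1 fell by 2.44 ± 0.48 and Mt2 fell by 4.54 ± 0.42. Cholesterol synthesis genes behaved as a block: 14 of 20 rose, 0 fell and 6 did not pass over all genes, against 17 and 0 adjusted over the list alone (median 1.78, cameraPR adjusted p = 3.2e-22, adjusted p = 0.015 with an estimated correlation). Within the slide that held both states its mean shifted by 1.73. Chaperones of the endoplasmic reticulum, led by Creld2 (2.71 ± 0.54) and Manf (2.47 ± 0.46), counted 13 of 19 rose and 0 fell, 17 and 0 adjusted over the list alone (median 1.09, adjusted p = 4e-22, adjusted p = 0.0066 with an estimated correlation). For ribosome biogenesis 7 of 21 rose and 0 fell, 13 and 0 adjusted over the list alone (median 0.49, adjusted p = 2.1e-12, adjusted p = 0.0066 with an estimated correlation), and for gluconeogenesis 0 of 11 rose and 3 fell, 0 and 6 adjusted over the list alone (median -0.48, adjusted p = 2.2e-05, adjusted p = 0.0038 with an estimated correlation). Fatty acid oxidation genes counted 0 of 25 rose and 4 fell, 0 and 13 adjusted over the list alone (median -0.55, adjusted p = 5.7e-11, adjusted p = 0.021 with an estimated correlation). Male-biased liver genes, which growth hormone pulses sustain, counted 4 of 14 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.99, adjusted p = 1.1e-10, adjusted p = 0.015 with an estimated correlation), with Nudt7 (2.86 ± 0.31) and Cyp7b1 (2.76 ± 0.48), and refed IRF.fl_Refed_467 lay at 13.0 (others 11.76 and 11.77). FoxO1 targets counted 0 of 20 rose and 6 fell, 2 and 8 adjusted over the list alone (median -0.29, adjusted p = 0.0015, adjusted p = 0.053 with an estimated correlation). In all, 796 genes changed (455 higher, 341 lower), and 567 with slide as a block. Left out in turn, the 6 libraries gave 1.47% (without IRF.fl_Fast_516) to 2.09% of genes (without IRF.fl_Fast_533), and 6 moved the count over 1.5 times. Igfbp1 (0.061 without IRF.fl_Fast_516) and Pck1 (0.0589 without IRF.fl_Refed_467) lost their calls with 1 mouse left out. The fasted side of these directions includes the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, and without it in any fit 461 genes changed and Irs2 no longer passed (-1.06 log2, adjusted p = 0.149).

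In LIRKO mice (n = 3 fasted, 4 refed) Pdk4, the kinase gene that restrains glucose oxidation, fell by 3.31 ± 0.35 log2 (adjusted p = 2.07e-06), Mt2 fell by 4.18 ± 0.42 and the glucose-sensing Txnip fell by 1.70 ± 0.24. The retinoic acid oxidase gene Cyp26a1 rose by 2.25 ± 0.42. Immediate early genes formed the clearest list: 0 of 18 rose, 4 fell and 14 did not pass over all genes, against 0 and 7 adjusted over the list alone (median -0.54, cameraPR adjusted p = 4.4e-12, adjusted p = 6.1e-04 with an estimated correlation), with Nr4a1 (-1.95 ± 0.26), Btg2 (-1.62 ± 0.28) and Klf6 (-1.40 ± 0.22). That list's mean shift was -0.337 and -0.821 within slides. Igfbp1 stayed at the top of the measuring range in every LIRKO group (15.96 ± 0.05 fasted and 15.95 ± 0.06 refed), so its change could not be read there. Pck1 (-0.01 ± 0.48, adjusted p = 0.997), G6pc (0.10 ± 0.48 log2, adjusted p = 0.974) and Irs2 (-0.30 ± 0.30 log2, adjusted p = 0.805) did not pass, and Pck1 could be read only in part, with libraries at the top in both states (15.86 fasted, 15.87 and 15.88 refed). Fatty acid oxidation genes counted 0 of 25 rose and 3 fell, 0 and 6 adjusted over the list alone (median -0.25, adjusted p = 5.2e-08, adjusted p = 0.16 with an estimated correlation). Macrophage and Kupffer cell markers counted 1 of 13 rose and 0 fell, 6 and 0 adjusted over the list alone (median 0.49, adjusted p = 3.2e-04, adjusted p = 0.42 with an estimated correlation). In cholesterol synthesis 0 of 20 rose and 0 fell, 0 and 0 adjusted over the list alone (median -0.17, adjusted p = 0.22, adjusted p = 0.87 with an estimated correlation). In all, 416 genes changed (221 higher, 195 lower), and 307 with slide as a block. The count was 191 without IR.KO_Fast_505, 271 without IR.KO_Refed_564, 226 without IR.KO_Fast_545, 270 without IR.KO_Refed_565 and 269 without IR.KO_Fast_550.

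In LIRFKO mice (n = 3 and 4) refeeding raised sterol genes, as in the IR/FoxO1 floxed mice of their line. Hmgcs1 rose by 2.43 ± 0.54 log2 (adjusted p = 0.0179), Aacs by 2.88 ± 0.55, Idi1 by 2.43 ± 0.60 and the fatty acid synthase gene Fasn by 1.496 ± 0.29 (adjusted p = 0.00804). Mt2 fell by 3.78 ± 0.39 and Pdk4 fell by 1.36 ± 0.32. Cholesterol synthesis genes counted as follows: 9 of 20 rose, 0 fell and 11 did not pass over all genes, against 16 and 0 adjusted over the list alone (median 1.56, cameraPR adjusted p = 2.4e-20, adjusted p = 0.029 with an estimated correlation), with a mean shift of 1.91 within the shared slide. For endoplasmic reticulum chaperones, with Creld2 (2.15 ± 0.50) and Manf (1.87 ± 0.43), 6 of 19 rose and 0 fell, 14 and 0 adjusted over the list alone (median 0.83, adjusted p = 2e-13, adjusted p = 0.045 with an estimated correlation). Of FoxO1 targets 0 of 20 rose and 2 fell, 1 and 3 adjusted over the list alone (median -0.58, adjusted p = 4.1e-05, adjusted p = 0.023 with an estimated correlation). Igfbp1 (-1.499 ± 0.73 log2, adjusted p = 0.367), G6pc (-1.04 ± 0.45 log2, adjusted p = 0.282) and Pck1 (-0.96 ± 0.45 log2, adjusted p = 0.329) did not pass. In all, 407 genes changed (222 higher, 185 lower), and 269 with slide as a block. The count was 168 without IRF.KO_Fast_519, 157 without IRF.KO_Refed_468, 138 without IRF.KO_Fast_518, 132 without IRF.KO_Refed_524 and 107 without IRF.KO_Fast_525. Hmgcs1 (0.111 without IRF.KO_Refed_524), Aacs (0.0551 without IRF.KO_Fast_518), Idi1 (0.155 without IRF.KO_Fast_518), Fasn (0.0674 without IRF.KO_Refed_524), Pdk4 (0.113 without IRF.KO_Fast_519), Creld2 (0.151 without IRF.KO_Fast_525) and Manf (0.134 without IRF.KO_Fast_525) lost their calls with 1 mouse left out.

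Differences between refeeding responses were then tested directly. Pdk4 fell more in LIRKO than in IR floxed mice, by -2.35 ± 0.44 log2 (adjusted p = 0.0221), and the response of the stress gene Herpud1 was lower as well (-2.29 ± 0.44). Cyp2c70 (-2.98 ± 0.64) and Osgin1 (-2.82 ± 0.58) differed the same way. For G6pc the difference was 2.18 ± 0.60 (adjusted p = 0.174), not past the threshold, and Igfbp1 could not be compared. Immediate early genes responded more negatively in LIRKO: 0 of 18 rose and 0 fell, 0 and 6 adjusted over the list alone (median -0.61, adjusted p = 4.3e-07, adjusted p = 0.028 with an estimated correlation). Gluconeogenesis genes responded less: 0 of 11 rose and 0 fell, 1 and 0 adjusted over the list alone (median 0.56, adjusted p = 7.1e-04, adjusted p = 0.028 with an estimated correlation). Between LIRFKO and LIRKO the cholesterol synthesis response differed: 0 of 20 rose and 0 fell, 17 and 0 adjusted over the list alone (median 1.75, adjusted p = 1.9e-26, adjusted p = 0.014 with an estimated correlation), and so did immediate early genes: 0 of 18 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.63, adjusted p = 4.8e-11, adjusted p = 0.0018 with an estimated correlation). Line and FoxO1 were not separated between LIRFKO and LIRKO. In LIRKO against IR floxed 37 genes changed (22 higher, 15 lower), and 16 with slide as a block. Left out in turn, the 15 libraries gave 3 (without IR.KO_Fast_505) to 60 (without IR.fl_Refed_566), and 12 moved the count over 1.5 times. Pdk4 (0.068 without IR.fl_Refed_562), Herpud1 (0.369 without IR.KO_Fast_505), Cyp2c70 (0.54 without IR.KO_Fast_505) and Osgin1 (0.537 without IR.KO_Fast_505) lost their calls with 1 mouse left out. In LIRFKO against LIRKO 5 genes changed, with Sorbs3 (1.001 ± 0.16) and Tnfrsf12a (1.68 ± 0.31) more positive and Ccr3 (-1.33 ± 0.18), Dusp14 and Epdr1 more negative. Left out in turn, the 14 libraries gave 2 (without IRF.KO_Fast_518) to 12 (without IR.KO_Fast_550), and 7 moved the count over 1.5 times. Sorbs3 (0.0891 without IRF.KO_Fast_518) and Tnfrsf12a (0.302 without IRF.KO_Fast_518) lost their calls with 1 mouse left out. Without IRF.fl_Fast_523 in any fit Tnfrsf12a (0.0628) did not pass. In LIRFKO against IR/FoxO1 floxed 1 gene, Clic5, changed and 912 had an unadjusted p under 0.05. Clic5 was named after its values were seen. The count was 2 without IRF.KO_Fast_518, IRF.fl_Refed_473 or IRF.KO_Refed_524 and 4 without IRF.fl_Refed_467. That comparison rests on the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, and without it 1 gene changed.

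Glucose for 60 min changed few genes in IR floxed mice (n = 4 and 3). The heat shock gene Hspa1a rose by 2.43 ± 0.35 log2 (adjusted p = 0.00143), the histone genes H3c15 and H2ac23 by 2.29 ± 0.47 and 1.65 ± 0.33, and the mitochondrial carrier gene Slc25a25 fell by 2.28 ± 0.48. G6pc (-1.76 ± 0.48 log2, adjusted p = 0.175) did not pass. Heat shock genes counted 1 of 9 rose, 0 fell and 8 did not pass over all genes, against 4 and 0 adjusted over the list alone (median 0.45, cameraPR adjusted p = 8.1e-07, adjusted p = 0.16 with an estimated correlation). Interferon response genes counted 0 of 17 rose and 0 fell, 0 and 1 adjusted over the list alone (median -0.66, adjusted p = 1.5e-08, adjusted p = 0.31 with an estimated correlation), and fasted IR.fl_Fast_486 lay at 8.987 in them (others 7.716 to 8.079). In all, 36 genes changed (32 higher, 4 lower), and 7 with slide as a block. The count was 14 without IR.fl_Fast_542, 5 without IR.fl_Fast_552, 3 without IR.fl_GTT_699, 384 without IR.fl_GTT_659, 11 without IR.fl_GTT_691 and 7 without IR.fl_Fast_491. H3c15 (0.23 without IR.fl_GTT_699), H2ac23 (0.203 without IR.fl_GTT_699) and Slc25a25 (0.204 without IR.fl_GTT_699) lost their calls with 1 mouse left out. Pancreatic acinar markers were high in IR.fl_Fast_486 (9.43, fasted) and IR.fl_GTT_659 (10.90, glucose), libraries of this comparison, and in IRF.KO_Refed_478 (11.42, LIRFKO refed). With all 3 left out of every fit 477 genes changed, and without IRF.fl_Fast_523 in any fit the adjusted p of Slc25a25 was 0.054.

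In LIRKO mice (n = 3 and 3) glucose also raised Hspa1a, by 1.88 ± 0.37 log2 (adjusted p = 0.0243). G0s2, an inhibitor of lipolysis, fell by 2.56 ± 0.54, the lipid transporter gene Mfsd2a fell by 2.70 ± 0.65, and Txnip fell by 1.29 ± 0.25. Immediate early genes counted 0 of 18 rose, 2 fell and 16 did not pass over all genes, against 0 and 5 adjusted over the list alone (median -0.33, cameraPR adjusted p = 0.0011, adjusted p = 0.4 with an estimated correlation), with Btg2 (-1.28 ± 0.30). In LIRFKO mice (n = 3 and 3) the histone genes H2ac4 and H2ac23 rose by 2.23 ± 0.24 (adjusted p = 5.07e-06) and 2.17 ± 0.33, Txnip fell by 1.43 ± 0.23, and the clock repressor genes Nr1d1 and Nr1d2 fell by 1.98 ± 0.42 and dropped by 1.55 ± 0.32. For gluconeogenesis 0 of 11 rose and 0 fell, 0 and 2 adjusted over the list alone (median -0.70, adjusted p = 1.5e-04, adjusted p = 0.015 with an estimated correlation). Neutrophil markers counted 0 of 8 rose and 0 fell, 5 and 0 adjusted over the list alone (median 0.85, adjusted p = 8.8e-05, adjusted p = 0.27 with an estimated correlation), and in 1 of the 3 glucose libraries, IRF.KO_GTT_726, they lay at 8.40 beside acute phase genes at 12.72. In LIRKO 134 genes changed (73 higher, 61 lower), and 187 with slide as a block. The count was 550 without IR.KO_GTT_697, 26 without IR.KO_Fast_505, 221 without IR.KO_GTT_667, 27 without IR.KO_Fast_550 and 5 without IR.KO_GTT_690. Hspa1a (0.112 without IR.KO_GTT_690), G0s2 (0.146 without IR.KO_Fast_550), Mfsd2a (0.352 without IR.KO_GTT_690), Txnip (0.207 without IR.KO_GTT_690) and Btg2 (0.217 without IR.KO_GTT_690) lost their calls with 1 mouse left out. Without IRF.fl_Fast_523 in any fit Mfsd2a (0.0556) and Btg2 (0.0554) did not pass. In LIRFKO 147 genes changed (77 higher, 70 lower), and 119 with slide as a block. The count was 60 without IRF.KO_GTT_726, 69 without IRF.KO_GTT_725 and 18 without IRF.KO_Fast_525. H2ac23 (0.0513 without IRF.KO_Fast_525), Txnip (0.13 without IRF.KO_Fast_525), Nr1d1 (0.196 without IRF.KO_Fast_525) and Nr1d2 (0.231 without IRF.KO_Fast_525) lost their calls with 1 mouse left out.

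Between LIRKO and IR floxed mice 0 glucose responses differed by limma (1542 genes at an unadjusted p under 0.05), and the count was 48 without IR.fl_GTT_659. Immediate early genes counted 0 of 18 rose and 0 fell, 0 and 4 adjusted over the list alone (median -0.50, adjusted p = 3e-05, adjusted p = 0.15 with an estimated correlation). Between LIRFKO and LIRKO 13 genes changed (6 higher, 7 lower), with Spdef (1.09 ± 0.19) and Sorbs3 (1.05 ± 0.17) higher and the succinate receptor gene Sucnr1 (-1.84 ± 0.36) lower. Left out in turn, the 12 libraries gave 1 (without IRF.KO_GTT_725) to 107 (without IR.KO_GTT_697), and 11 moved the count over 1.5 times. Spdef (0.158 without IRF.KO_Fast_518), Sorbs3 (0.0938 without IRF.KO_GTT_725) and Sucnr1 (0.164 without IR.KO_Fast_550) lost their calls with 1 mouse left out. Without IRF.fl_Fast_523 in any fit Sucnr1 (0.0549) did not pass. Refeeding and glucose responses share their fasted mice. In IR floxed mice 6 genes changed in both (3 higher, 3 lower), where independent lists give 0.679 and 0.0594. In LIRKO 16 changed in both (1 higher, 12 lower, 3 opposite), against 0.718 and 0.529 for independent lists. In LIRFKO 23 changed in both (8 higher, 15 lower), against 0.76 and 0.576. Simulated unchanged groups on the shared mice shared 0, since they gave hardly any calls. The covariance of both responses over genes was 0.00688 in IR floxed, 0.0052 in LIRKO and 0.0165 in LIRFKO mice, against 0.0121, 0.0174 and 0.0136 simulated. When the 4 fasted IR floxed mice were divided between both responses, the 6 divisions gave 0 to 4 shared genes, 0 to 1 of the same sign, and a median covariance of -0.0074.

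Loss of the insulin receptor in fasted liver (3 LIRKO against 4 IR floxed mice) raised Pdk4 by 3.78 ± 0.33 log2 (adjusted p = 4.82e-08) and lowered Igf1, which fell by 2.41 ± 0.27 (adjusted p = 1.58e-06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 4.94 ± 0.57 and Scd1 fell by 2.49 ± 0.50, while Txnip rose by 2.44 ± 0.22 and the protease inhibitor gene Slpi by 4.33 ± 0.45. Insr fell by 1.76 ± 0.23 (adjusted p = 1.32e-05), Irs2 rose by 1.05 ± 0.29 and Igfbp1, at the top of the range in LIRKO, rose by at least 2.10 between group means (adjusted p = 0.0319 in the fit). Pck1 (-0.04 ± 0.45 log2, adjusted p = 0.98) and G6pc (-0.56 ± 0.45 log2, adjusted p = 0.57) did not pass, with Pck1 at the top of the range in 1 library of each group. Male-biased liver genes, with Cyp4a12a (-2.55 ± 0.39), counted 0 of 14 rose, 6 fell and 8 did not pass over all genes, against 0 and 10 adjusted over the list alone (median -1.42, cameraPR adjusted p = 8.1e-09, adjusted p = 0.045 with an estimated correlation), and their mean shift within slides was -2.36 and -1.44. Female-biased genes, with Cyp2b13 (2.54 ± 0.44), counted 3 of 14 rose and 0 fell, 6 and 0 adjusted over the list alone (median 0.43, adjusted p = 0.0016, adjusted p = 0.13 with an estimated correlation). Immediate early genes, with Nr4a1 (1.84 ± 0.25) and Klf6 (1.44 ± 0.21), counted 9 of 18 rose and 0 fell, 12 and 0 adjusted over the list alone (median 0.69, adjusted p = 6.5e-08, adjusted p = 0.013 with an estimated correlation), with mean shifts of 1.07 and 0.779 within slides. Of bile acid and sterol transport genes, with Slc10a2 (-3.03 ± 0.27) and Cyp8b1 (-2.36 ± 0.48), 0 of 16 rose and 7 fell, 1 and 9 adjusted over the list alone (median -0.51, adjusted p = 3.3e-06, adjusted p = 0.0074 with an estimated correlation). Fatty acid oxidation genes, with Acot2 (2.70 ± 0.36), counted 7 of 25 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.50, adjusted p = 3.6e-08, adjusted p = 0.077 with an estimated correlation). In all, 1813 genes changed (931 higher, 882 lower), and 1852 with slide as a block. The count was 1089 without IR.KO_Fast_505, 1061 without IR.KO_Fast_550 and 1181 without IR.fl_Fast_486. Irs2 (0.0956 without IR.KO_Fast_545), Igfbp1 (0.146 without IR.KO_Fast_550) and Cyp8b1 (0.115 without IR.KO_Fast_505) lost their calls with 1 mouse left out.

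In refed liver (4 LIRKO, 4 IR floxed) Igfbp1 rose by at least 5.66 log2 between group means (adjusted p = 8.37e-07 in the fit), Irs2 by 1.99 ± 0.26, Ppargc1a by 1.68 ± 0.38, G6pc by 1.62 ± 0.42 (adjusted p = 0.0088) and Pck1 by 1.41 ± 0.41 (adjusted p = 0.0235), with 2 of the 4 LIRKO libraries at the top of the range (15.87 and 15.88). Igf1 fell by 2.74 ± 0.25, the bile acid transporter gene Slc10a2 fell by 4.36 ± 0.25 (adjusted p = 2.58e-12), and Srebf1 fell by 0.66 ± 0.21. H19 and Tff3 rose by 4.05 ± 0.64 and 4.23 ± 0.92. Male-biased genes counted 0 of 14 rose, 9 fell and 5 did not pass over all genes, against 0 and 11 adjusted over the list alone (median -1.48, cameraPR adjusted p = 3.3e-16, adjusted p = 0.0035 with an estimated correlation), with Cyp4a12a (-3.97 ± 0.36) and within-slide mean shifts of -1.96, -1.15 and -2.55. Female-biased genes, with Cyp2b13 (2.95 ± 0.41), counted 9 of 14 rose and 0 fell, 9 and 0 adjusted over the list alone (median 1.10, adjusted p = 6.8e-07, adjusted p = 0.011 with an estimated correlation). Macrophage and Kupffer cell markers, with Cd5l (1.88 ± 0.28), Vsig4 (1.56 ± 0.25) and C1qa (1.33 ± 0.21), counted 11 of 13 rose and 0 fell, 12 and 0 adjusted over the list alone (median 1.28, adjusted p = 3.3e-16, adjusted p = 0.0071 with an estimated correlation), and lay at 9.30 ± 0.05 (SD) against 8.10 ± 0.15 in IR floxed mice, with within-slide mean shifts of 1.11, 1.05 and 1.41. Of cholesterol synthesis genes, with Insig1 (-1.86 ± 0.46) and Tm7sf2 (-1.69 ± 0.25), 0 of 20 rose and 8 fell, 0 and 12 adjusted over the list alone (median -1.09, adjusted p = 5.9e-09, adjusted p = 0.19 with an estimated correlation), and within slides the mean shift was -0.799, 0.0317 and -1.30. FoxO1 targets counted 7 of 20 rose and 2 fell, 9 and 2 adjusted over the list alone (median 0.20, adjusted p = 0.03, adjusted p = 0.21 with an estimated correlation), and fatty acid oxidation genes 13 of 25 rose and 0 fell, 15 and 0 adjusted over the list alone (median 0.88, adjusted p = 6.8e-07, adjusted p = 0.12 with an estimated correlation). In all, 2610 genes changed (1562 higher, 1048 lower), and 2732 with slide as a block. The count was 1710 without IR.KO_Refed_553 and 1729 without IR.fl_Refed_562. G6pc (0.122 without IR.fl_Refed_562), Pck1 (0.088 without IR.fl_Refed_566) and Srebf1 (0.184 without IR.fl_Refed_508) lost their calls with 1 mouse left out.

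After glucose (3 LIRKO, 3 IR floxed) Irs2 was higher by 2.62 ± 0.30 log2 (adjusted p = 3.86e-06), G6pc by 2.18 ± 0.48 (adjusted p = 0.00463), Pdk4 by 2.03 ± 0.35 and Igfbp1 by at least 2.12 between group means (adjusted p = 0.0294 in the fit). Igf1 fell by 2.45 ± 0.29, Insr fell by 1.19 ± 0.24 and Scd1 fell by 2.72 ± 0.53. Amino acid catabolism and urea cycle genes, with Aass (-2.51 ± 0.45), Tdo2 (-1.87 ± 0.32) and Prodh (-1.49 ± 0.23), counted 0 of 20 rose, 10 fell and 10 did not pass over all genes, against 0 and 12 adjusted over the list alone (median -0.95, cameraPR adjusted p = 1.7e-11, adjusted p = 0.047 with an estimated correlation), and their mean shift within slides was -1.14 and -0.989. Hepatocyte markers (14.79 against 15.28) and periportal hepatocyte genes (12.11 against 12.80) were lower in the same mice, with mean shifts within slides of -0.643 and -0.678, and -0.72 and -1.01. ChREBP-responsive genes, with Txnip (1.90 ± 0.24), counted 5 of 14 rose and 0 fell, 6 and 0 adjusted over the list alone (median 0.74, adjusted p = 3e-04, adjusted p = 0.047 with an estimated correlation). Male-biased genes counted 0 of 14 rose and 7 fell, 0 and 9 adjusted over the list alone (median -1.15, adjusted p = 1.4e-08, adjusted p = 0.059 with an estimated correlation). In all, 1866 genes changed (986 higher, 880 lower), and 1847 with slide as a block. The count was 909 without IR.KO_GTT_690. Igfbp1 (0.147 without IR.fl_GTT_659) lost its call with 1 mouse left out.

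**Figure D2:**
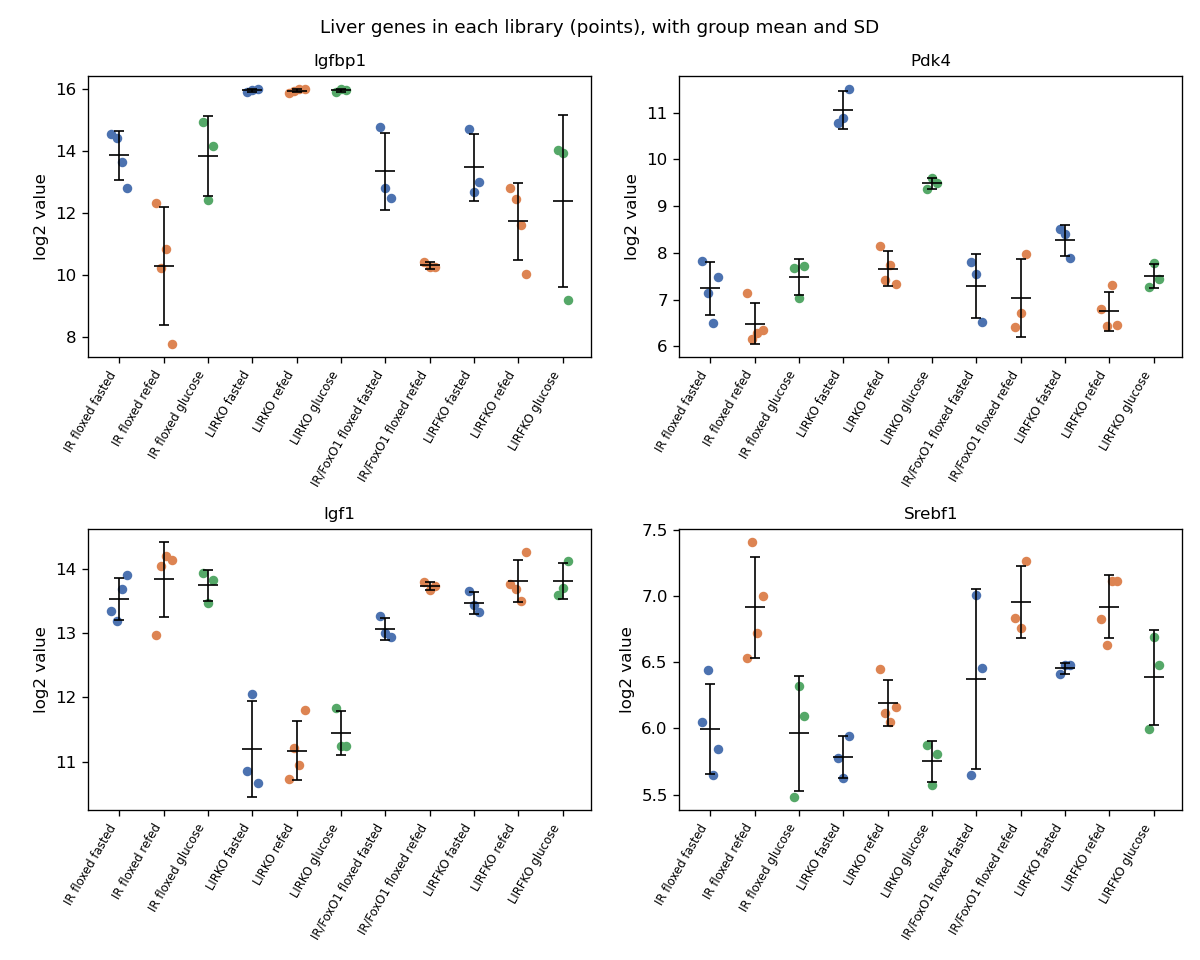
Igfbp1, Pdk4, Igf1 and Srebf1 in each library as log2 values (points; blue fasted, orange refed, green glucose), with group mean and SD as bars. Igfbp1 sits at the top of the range in all 3 LIRKO groups (15.95 to 15.96), Pdk4 is at 11.06 in fasted LIRKO against 7.24 in fasted IR floxed mice, and Igf1 is lower in LIRKO (11.17 to 11.45) than in the other groups.

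With FoxO1 deleted too, few knockout effects passed in fasted mice (3 LIRFKO against 3 IR/FoxO1 floxed). Foxo1 (-2.44 ± 0.50 log2, adjusted p = 0.254) and Insr (-0.99 ± 0.25 log2, adjusted p = 1) did not pass, and 1 gene, 1700113H08Rik, changed, with 819 at an unadjusted p under 0.05. The control side includes the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523. Without it 9 genes changed, among them Foxo1, which fell by 3.56 ± 0.23 (adjusted p = 1.65e-10), Insr, which fell by 1.39 ± 0.22 (adjusted p = 0.00564), Pcsk6, which fell by 1.07 ± 0.16, and Mmd2, which rose by 2.26 (adjusted p = 0.0173). Igfbp1 (-0.45), Igf1 (0.54), Irs2 (0.03) and Pdk4 (0.81) did not pass there. Male-biased genes counted 0 of 14 rose, 0 fell and 14 did not pass over all genes, against 0 and 0 adjusted over the list alone (median 0.38, cameraPR adjusted p = 1.6e-04, adjusted p = 0.65 with an estimated correlation). With slide as a block 0 genes changed. The count was 2 without IRF.KO_Fast_519, 3 without IRF.KO_Fast_518 and 0 without IRF.fl_Fast_516, IRF.KO_Fast_525 or IRF.fl_Fast_533.

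In refed mice (4 LIRFKO, 3 IR/FoxO1 floxed) Foxo1 fell by 2.996 ± 0.46 log2 (adjusted p = 0.00141) and Insr fell by 1.56 ± 0.23 (adjusted p = 0.00121). The asparagine synthetase gene Asns rose by 3.28 ± 0.75 (adjusted p = 0.0475) and Mmd2 by 2.24 ± 0.47, while the water channel gene Aqp8 fell by 2.82 ± 0.48 and Cyp2c70 fell by 2.17 ± 0.49. Without IRF.fl_Fast_523 in any fit, Asns (adjusted p = 0.0692) and Cyp2c70 (adjusted p = 0.0724) no longer passed. Igfbp1 (1.66 ± 0.77 log2, adjusted p = 0.441) and Igf1 (-0.16 ± 0.28 log2, adjusted p = 0.904) did not pass. Stellate cell and fibroblast markers counted 0 of 11 rose, 0 fell and 11 did not pass over all genes, against 4 and 0 adjusted over the list alone (median 0.39, cameraPR adjusted p = 5.6e-06, adjusted p = 0.05 with an estimated correlation). Acinar markers counted 0 of 7 rose and 0 fell, 0 and 0 adjusted over the list alone (median 1.19, adjusted p = 0.032, adjusted p = 0.66 with an estimated correlation), and their median was -0.0707 with IR.fl_Fast_486, IR.fl_GTT_659 and IRF.KO_Refed_478 left out. In all, 85 genes changed (33 higher, 52 lower). With slide as a block 85 changed, of which 59 were the same genes, and no slide held both groups. The count was 55 without IRF.fl_Refed_472, 40 without IRF.KO_Refed_468, 26 without IRF.fl_Refed_473 and 33 without IRF.fl_Refed_467. Asns (0.189 without IRF.fl_Refed_472), Mmd2 (0.246 without IRF.fl_Refed_473), Aqp8 (0.0625 without IRF.fl_Refed_467) and Cyp2c70 (0.203 without IRF.KO_Refed_468) lost their calls with 1 mouse left out.

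Genes changed in LIRKO were then read in LIRFKO against its own controls, which share no mice. Of 1813 genes changed in fasted LIRKO, 63.6% had the same sign in LIRFKO and 0 changed in both. Without IRF.fl_Fast_523 the same sign held for 71.4% of 1861 genes, and 5 of the 9 genes changed in LIRFKO changed in both. LIRFKO medians were 0.04 for genes higher in LIRKO (0.61 there) and -0.06 for lower ones (-0.70), and 0.1 and -0.112 without that library. Choosing by LIRKO enlarges its medians. Of 2610 genes changed in refed LIRKO, 80.2% had the same sign in LIRFKO, with medians of 0.155 against 0.605 and -0.188 against -0.616. There 47 genes changed in both, 45 with the same sign.

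The difference between both knockout effects was tested gene by gene. In fasted mice (13 libraries) Igf1 was higher by 2.99 ± 0.38 log2 (adjusted p = 1.67e-04) with FoxO1 also deleted and Pdk4 lower (-3.06 ± 0.47, adjusted p = 6.34e-04). Cyp7a1 (4.69 ± 0.81) and Cyp7b1 (3.89 ± 0.64), both of bile acid synthesis, were higher and Txnip (-2.17 ± 0.32) lower. Male-biased genes counted 3 of 14 rose, 0 fell and 11 did not pass over all genes, against 10 and 0 adjusted over the list alone (median 2.06, cameraPR adjusted p = 1.9e-15, adjusted p = 0.0045 with an estimated correlation). For bile acid and sterol transport 2 of 16 rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.59, adjusted p = 4.3e-05, adjusted p = 0.012 with an estimated correlation), and for the growth hormone and IGF axis 2 of 10 rose and 0 fell, 3 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.0035, adjusted p = 0.016 with an estimated correlation). In refed mice (15 libraries) Slc10a2 was higher (3.83 ± 0.37, adjusted p = 3.79e-07), as was Igf1 (2.57 ± 0.37), and Igfbp1 (a bound of -4.24 between group means, adjusted p = 0.0286 in the fit), Irs2 (-1.58 ± 0.39) and Igfbp2 (-2.27 ± 0.33) were lower. Macrophage markers counted 0 of 13 rose and 0 fell, 0 and 9 adjusted over the list alone (median -0.81, adjusted p = 5.3e-07, adjusted p = 0.13 with an estimated correlation), and female-biased genes 0 of 14 rose and 1 fell, 0 and 5 adjusted over the list alone (median -1.02, adjusted p = 9.1e-06, adjusted p = 0.078 with an estimated correlation). In fasted mice 210 genes changed (101 higher, 109 lower), 239 with slide as a block and 132 without the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, in any fit. The count was 119 without IRF.KO_Fast_518, 111 without IR.fl_Fast_491 and 102 without IR.KO_Fast_550. Without IRF.fl_Fast_523 the differences of Cyp2b9 (-2.87, adjusted p = 0.074) and Ghr (1.51, adjusted p = 0.103) no longer passed. In refed mice 297 genes changed (194 lower), 229 with slide as a block. The count was 184 without IR.KO_Refed_553, 651 without IR.fl_Refed_566, 180 without IRF.fl_Refed_472 and 151 without IRF.fl_Refed_467. Igfbp1 (0.132 without IRF.fl_Refed_467) and Irs2 (0.108 without IR.KO_Refed_553) lost their calls with 1 mouse left out.

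LIRFKO was also set directly against LIRKO, whose libraries serve in both comparisons, so opposite signs to the LIRKO effects are not independent evidence. In fasted mice (3 and 3) Foxo1 fell by 3.47 ± 0.48 log2 (adjusted p = 3.41e-05), Igfbp1 was lower by a bound of -2.49 between group means (adjusted p = 0.0106 in the fit), Pdk4 fell by 2.83 ± 0.35, Igf1 rose by 2.52 ± 0.29 and Cyp7a1 by 4.30 ± 0.60. Irs2 fell by 1.002 ± 0.30 (adjusted p = 0.0442, and 0.0504 without IRF.fl_Fast_523 in any fit). Immediate early genes counted 0 of 18 rose, 6 fell and 12 did not pass over all genes, against 0 and 12 adjusted over the list alone (median -0.53, cameraPR adjusted p = 1.5e-07, adjusted p = 0.016 with an estimated correlation), with a mean shift of -0.789 within the shared slide, and glycogen metabolism genes 1 of 9 rose and 5 fell, 2 and 5 adjusted over the list alone (median -0.74, adjusted p = 0.044, adjusted p = 0.12 with an estimated correlation). Male-biased genes, with Cyp4a12a (2.91 ± 0.42), counted 5 of 14 rose and 0 fell, 8 and 0 adjusted over the list alone (median 1.41, adjusted p = 1.3e-07, adjusted p = 0.062 with an estimated correlation). In all, 1466 genes changed (739 higher), and 1648 with slide as a block. The count was 532 without IRF.KO_Fast_518, 977 without IRF.KO_Fast_525 and 510 without IR.KO_Fast_550. Igfbp1 (0.16 without IRF.KO_Fast_518) and Irs2 (0.145 without IR.KO_Fast_545) lost their calls with 1 mouse left out.

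In refed mice (4 and 4) sterol synthesis genes were higher in LIRFKO than in LIRKO, and floxed controls of the 2 lines differed likewise. Sqle rose by 4.43 ± 0.68 log2 (adjusted p = 8.41e-05), Hmgcs1 by 4.14 ± 0.50 (adjusted p = 2.62e-06), and Fasn (1.37 ± 0.27) and Srebf1 (0.71 ± 0.21) by less. Igfbp1 was lower by a bound of -4.22 between group means (adjusted p = 6.6e-05 in the fit), Irs2 fell by 1.38 ± 0.26 and Igf1 rose by 2.59 ± 0.25. Cholesterol synthesis genes counted 20 of 20 rose, 0 fell and 0 did not pass over all genes, against 20 and 0 adjusted over the list alone (median 2.18, cameraPR adjusted p = 5.1e-44, adjusted p = 5e-04 with an estimated correlation), with within-slide mean shifts of 2.39, 2.41 and 2.25. Male-biased genes counted 9 of 14 rose and 0 fell, 11 and 0 adjusted over the list alone (median 1.49, adjusted p = 2.7e-15, adjusted p = 0.0019 with an estimated correlation), and female-biased genes, with Cyp2b9 (-2.91 ± 0.47), 0 of 14 rose and 7 fell, 0 and 9 adjusted over the list alone (median -1.04, adjusted p = 1.7e-07, adjusted p = 0.0044 with an estimated correlation). Macrophage markers, with C1qa (-0.74 ± 0.21) and Clec4f (-1.04 ± 0.24), counted 0 of 13 rose and 8 fell, 0 and 12 adjusted over the list alone (median -0.74, adjusted p = 1.7e-07, adjusted p = 0.084 with an estimated correlation), at 8.57 ± 0.21 (SD) in LIRFKO. In all, 1820 genes changed (824 higher, 996 lower), and 1604 with slide as a block. The count was 1065 without IRF.KO_Refed_468 and 1118 without IR.KO_Refed_565. Srebf1 (0.12 without IR.KO_Refed_565) and C1qa (0.116 without IRF.KO_Refed_478) lost their calls with 1 mouse left out. After glucose (3 and 3) Igf1 rose by 2.43 ± 0.29, G6pc fell by 1.84 ± 0.48 (adjusted p = 0.017) and Insr fell by 0.84 ± 0.24 (adjusted p = 0.0295). FoxO1 targets counted 1 of 20 rose and 6 fell, 1 and 6 adjusted over the list alone (median -0.26, adjusted p = 2.6e-04, adjusted p = 0.068 with an estimated correlation). There 1703 genes changed (865 higher, 838 lower), and 1551 with slide as a block. The count was 621 without IRF.KO_GTT_725 and 989 without IR.KO_GTT_690. G6pc (0.17 without IRF.KO_GTT_725) and Insr (0.161 without IRF.KO_GTT_725) lost their calls with 1 mouse left out.

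**Figure D3:**
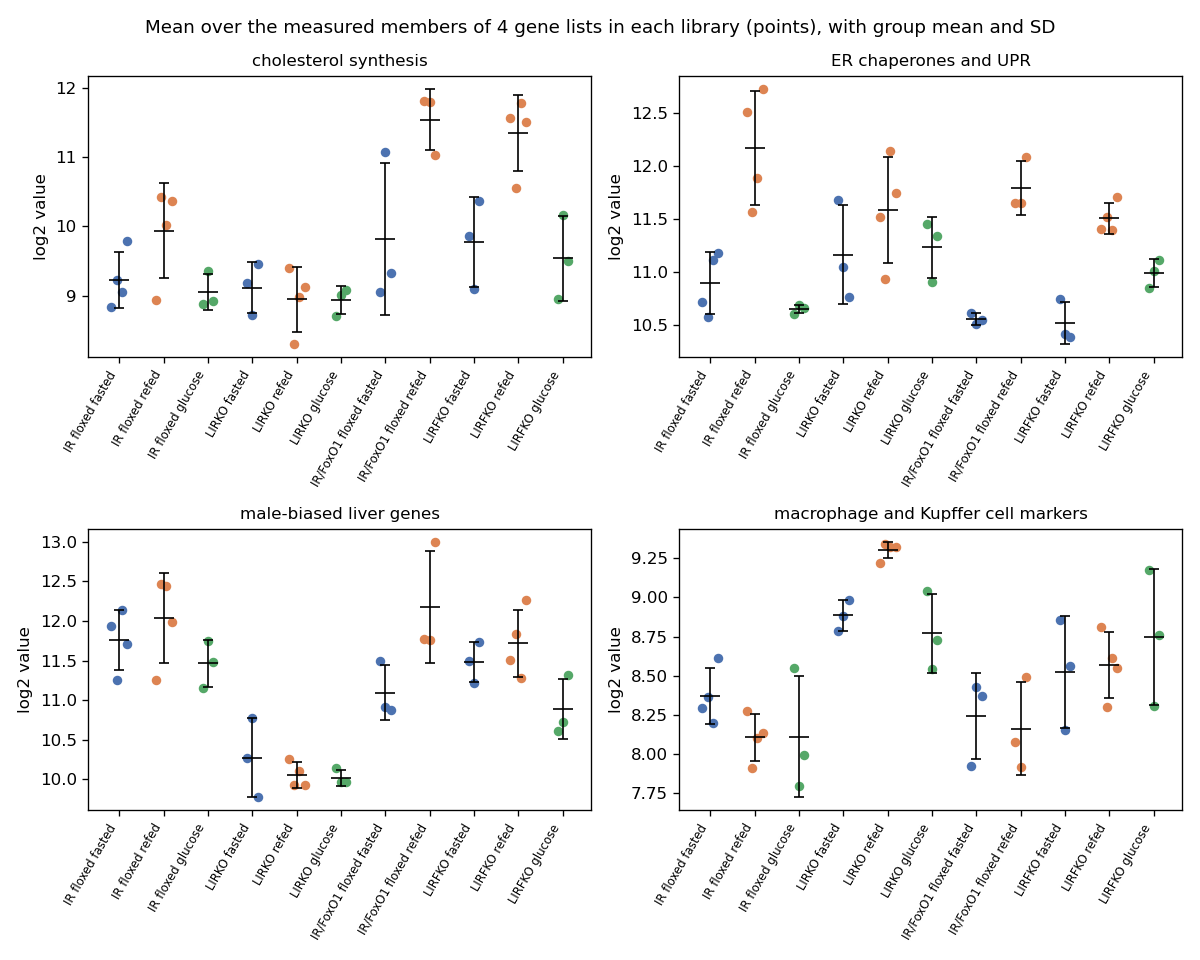
Mean log2 value over the measured members of 4 gene lists in each library (points; blue fasted, orange refed, green glucose), with group mean and SD as bars. Cholesterol synthesis genes average 11.35 in refed LIRFKO and 11.54 in refed IR/FoxO1 floxed mice against 8.95 in refed LIRKO, and macrophage markers are at 9.30 in refed LIRKO.

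The floxed controls differed from each other in sterol genes. In refed mice (3 IR/FoxO1 floxed, 4 IR floxed) Dhcr7 rose by 1.85 ± 0.28 log2 (adjusted p = 0.00235), Hsd17b7 by 1.56 ± 0.27, the erythroid factor gene Nfe2 by 2.16 ± 0.23 and Dcun1d1 by 2.09 ± 0.34, and Mt2 fell by 2.27 ± 0.39. Cholesterol synthesis genes counted 2 of 20 rose, 0 fell and 18 did not pass over all genes, against 19 and 0 adjusted over the list alone (median 1.72, cameraPR adjusted p = 7.1e-43, adjusted p = 6.5e-04 with an estimated correlation). In fasted mice (3 and 4) Dcun1d1 rose by 2.01 ± 0.34 (adjusted p = 0.0185) and Cyp2g1 by 2.03 ± 0.34. Pericentral hepatocyte genes counted 0 of 11 rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.43, adjusted p = 5e-05, adjusted p = 0.026 with an estimated correlation). The fasted directions rest on a group that holds the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, and without it 2 genes changed and Cyp2g1 (0.277) did not pass. In refed mice 19 genes changed (16 higher, 3 lower), 15 with slide as a block. The count was 7 without IRF.fl_Refed_472, 9 without IRF.fl_Refed_473 and 11 without IR.fl_Refed_506. Hsd17b7 (0.0967 without IRF.fl_Refed_473) and Mt2 (0.0867 without IR.fl_Refed_566) lost their calls with 1 mouse left out. In fasted mice 8 genes changed (5 higher, 3 lower), 5 with slide as a block. The count was 1 without IR.fl_Fast_552 or IR.fl_Fast_491, 18 without IRF.fl_Fast_516 and 0 without IR.fl_Fast_486 or IRF.fl_Fast_533. Dcun1d1 (0.129 without IRF.fl_Fast_533) and Cyp2g1 (0.277 without IRF.fl_Fast_523) lost their calls with 1 mouse left out.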

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

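All 7 tests of explanations in this part were chosen after the result was seen, and the tests for lone samples and for differences between responses were planned.

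Single libraries stood apart from the other 3 of their group in 12 of 204 tests over the 4 groups of 4 mice, where chance gives about 1 in 20. Pancreatic acinar markers lay at 9.43 in fasted IR floxed library IR.fl_Fast_486, against 6.073 to 6.611 in the others, and at 11.42 in refed LIRFKO library IRF.KO_Refed_478, against 5.986 to 6.121. In IR.fl_Fast_486 adipocyte markers lay at 5.59 (others 5.533 to 5.535), and in IRF.KO_Refed_478 pentose phosphate genes lay at 9.591 (others 9.837 to 9.874). Fasted IR floxed library IR.fl_Fast_491 was low in stellate cell and fibroblast markers (6.95, others 7.243 to 7.292) and in Foxo1 (9.979, others 10.44 to 10.5). Refed IR floxed library IR.fl_Refed_566 was high in ATF4 and integrated stress response genes (8.728, others 8.269 to 8.339) and low in Igf1 (12.97, others 14.04 to 14.2). Refed LIRKO library IR.KO_Refed_564 was high in interferon response genes (8.355, others 7.968 to 8.017) and low in hepatocyte markers (14.17, others 14.97 to 15.11). Refed LIRKO library IR.KO_Refed_553 was low in macrophage and Kupffer cell markers (9.224, others 9.323 to 9.341) and in Pck1 (14.43, others 15.67 to 15.88).

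In tests of differences, refeeding moved Pdk4 by -2.349 log2 in LIRKO relative to IR floxed mice. The knockout effect with FoxO1 also deleted differed from that without by -3.055 for Pdk4 and 2.991 for Igf1 in fasted mice, a comparison that holds the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523. In refed mice it differed by -2.667 for Foxo1 itself, by -4.219 in the fit for Igfbp1, which was at the top of the range in LIRKO, by -1.584 for Irs2 and by 2.571 for Igf1. Among lists, the refeeding responses of LIRKO and IR floxed mice differed by a median of 0.556 for gluconeogenesis and -0.606 for immediate early genes. Those of LIRFKO and LIRKO differed by 1.75 for cholesterol synthesis and 0.634 for immediate early genes, with line and FoxO1 not separated. Knockout effects in fasted mice differed with FoxO1 also deleted by 0.589 for bile acid and sterol transport, 0.249 for the growth hormone and IGF axis and 2.06 for male-biased liver genes. Outside the named genes, 5.72% of the 12194 features without a gene name changed in refed LIRKO against IR floxed mice.

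The library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, differed from the mean of the other fasted mice of its group by -3.60 log2 in Foxo1 and -1.31 in Insr. On a scale over 83 genes changed in the refed comparison, with the floxed mean at 0 and the LIRFKO mean at 1, it lay at 0.963, where the others of its group lay at 0.229 and -0.298 and the fasted LIRFKO libraries at 1.03, 0.94 and 1.03. A failed hybridization is argued against, since among the 2740 genes at least as bright as Foxo1, itself included, 0 others lay as far below. A swap with a library labelled LIRFKO is argued against too, since 0 of the 10 LIRFKO libraries had Foxo1 in the range of the others, the highest being 7.118 against 9.14. A mouse with both genes deleted may have been labelled as a control, which the 0.963 fits and which stays a hypothesis.

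Macrophage and Kupffer cell markers were higher by 1.20 log2 on average in refed LIRKO than in refed IR floxed mice. Hepatocyte markers, some at the top of the range, lay at 14.82 ± 0.433 (SD) against 15.34 ± 0.107, with 1 LIRKO library at 14.17 and the other 3 at 14.97 to 15.11, so a lower share of hepatocyte RNA in some of these mice stays possible. It would raise the markers of other cell types alike, and as the whole cause it is argued against, since the macrophage shift exceeded the endothelial (0.188), stellate (0.267) and lymphocyte (0.107) shifts by at least 0.932 (SE 0.178). Over the neutrophil shift (-0.0909) the excess was 1.29 (SE 0.108), which argues against neutrophils in blood. Other blood cells stay open, with 0.688 (SE 0.389) over the erythroid shift (0.512). More resident macrophages and more marker RNA in each stay candidates, not separated here.

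Male-biased liver genes were lower and female-biased ones higher in refed LIRKO than in refed IR floxed mice. Female mice among the LIRKO libraries are argued against, since the highest Xist value there was 5.455, near the floor of the arrays and under the highest of the IR floxed libraries (5.478). Lower growth hormone signalling to STAT5 stays open: 2 of 4 STAT5 targets fell in refed LIRKO, Igf1 (-2.74) and Igfals (-1.89), while Socs2 (0.63, adjusted p = 0.606) and Cish (0.790, adjusted p = 0.515) did not pass. The genotype is the biological difference that the design names, and it stays among the open explanations.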

How the results depend on the processing

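Of the alternatives, the fits without IRF.fl_Fast_523 and without IR.fl_Fast_486, IR.fl_GTT_659 and IRF.KO_Refed_478 (the acinar libraries) were chosen after the data were seen; the others were planned. No paired analysis was possible because the groups share no mouse numbers.

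Named genes mostly stayed past the threshold. With slide as a block 664 named results stayed and 97 weakened, without the dye term 642 and 119, with quantile normalization 757 and 4, with the mean of all probes 721 and 40, without IRF.fl_Fast_523 708 and 53, and without the acinar libraries 666 and 95. With each mouse left out in turn 1454 stayed and 534 weakened. None of these reversed. Of 233 list calls 212 stayed with slide as a block, 227 without the dye term, 233 with quantile normalization, 218 without IRF.fl_Fast_523 and 202 without the acinar libraries, and 44 with an estimated correlation. Within slides 122 of 157 median shifts stayed, 32 moved and 3 reversed. Those 3 were amino acid catabolism and urea cycle genes on refeeding in IR floxed mice (0.0115), cholesterol synthesis in fasted LIRFKO against LIRKO (-0.534) and neutrophil markers after glucose in LIRFKO against LIRKO (-0.0166). ChREBP-responsive genes on refeeding in IR/FoxO1 floxed mice reversed without IRF.fl_Fast_523 (0.0432), and pancreatic acinar markers in refed LIRFKO against IR/FoxO1 floxed mice reversed without the acinar libraries (-0.0707). The same sign of the knockout effect with and without FoxO1 went from 63.6% of genes in fasted mice to 71.4% without IRF.fl_Fast_523 and 61.4% for an adjusted p under 0.01 and at least 1 log2, and in refed mice from 80.2% to 79.1% and 86.3%.

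Counts of changed genes moved more, and are given as percent of the 22485 genes. Without the array block the shares that moved by more than 1.5 times were 2.19% for refeeding in IR/FoxO1 floxed, 0.974% for refeeding in LIRFKO, 0.0756% for glucose in IR floxed and 0.0889% for glucose in LIRKO. Glucose in LIRFKO was at 0.191%, beside 5.43% for LIRKO against IR floxed (glucose), 0% for LIRFKO against IR/FoxO1 floxed (fasted) and 0.227% for LIRFKO against IR/FoxO1 floxed (refed). LIRFKO against LIRKO (fasted) was at 3.76%, beside 0.0222% for the refeeding difference of LIRKO against IR floxed, 0.00889% for the refeeding difference of LIRFKO against LIRKO and 0% for the glucose difference of LIRFKO against LIRKO. IR/FoxO1 floxed against IR floxed (fasted) was at 0%, beside 0.391% for FoxO1 dependence (fasted). Dropping the dye term gave 2.25% for refeeding in IR/FoxO1 floxed, 1.17% for refeeding in LIRFKO, 0.191% for glucose in LIRKO and 0.262% for glucose in LIRFKO. LIRFKO against IR/FoxO1 floxed (fasted) was at 0%, beside 0.04% for the refeeding difference of LIRKO against IR floxed, 0.0133% for the refeeding difference of LIRFKO against LIRKO and 0.00889% for the glucose difference of LIRFKO against LIRKO. IR/FoxO1 floxed against IR floxed (fasted) was at 0%, beside 0.0534% for IR/FoxO1 floxed against IR floxed (refed) and 0.592% for FoxO1 dependence (fasted). Slide as a fixed block gave 1.2% for refeeding in LIRFKO, 0.0311% for glucose in IR floxed, 0% for LIRFKO against IR/FoxO1 floxed (fasted) and 0.0712% for the refeeding difference of LIRKO against IR floxed. The refeeding difference of LIRFKO against IR/FoxO1 floxed was at 0%, beside 0.0222% for IR/FoxO1 floxed against IR floxed (fasted). Centring each channel on its median gave 0.0489% for glucose in IR floxed and 0.00889% for LIRFKO against IR/FoxO1 floxed (fasted). Trend and robust eBayes gave 0.351% for glucose in LIRKO, 0.0489% for the refeeding difference of LIRFKO against LIRKO, 0.0311% for the glucose difference of LIRFKO against LIRKO and 0.0133% for IR/FoxO1 floxed against IR floxed (fasted). The mean of all probes gave 0.0311% for the glucose difference of LIRFKO against LIRKO and 0% for IR/FoxO1 floxed against IR floxed (fasted). Leaving out the lowest 40% of genes gave 0.0178% for IR/FoxO1 floxed against IR floxed (fasted). Quantile normalization moved no count by that much. Beyond the construction of each alternative, the cause was not tested.

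Fitting the compared groups alone, which leaves fewer samples for the spread, gave 0.614% for refeeding in IR floxed, 2.25% for refeeding in IR/FoxO1 floxed, 0.756% for refeeding in LIRKO and 0.365% for refeeding in LIRFKO. Glucose was at 0% in IR floxed, LIRKO and LIRFKO, beside 2.48% for LIRKO against IR floxed (fasted). LIRKO against IR floxed (glucose) was at 0.0222%, beside 0% for LIRFKO against IR/FoxO1 floxed (fasted), 0.0222% for LIRFKO against IR/FoxO1 floxed (refed) and 0.36% for LIRFKO against LIRKO (fasted). LIRFKO against LIRKO (glucose) was at 2.24%, beside 0.0267% for the refeeding difference of LIRKO against IR floxed, 0% for the refeeding difference of LIRFKO against IR/FoxO1 floxed and 0% for the glucose difference of LIRFKO against LIRKO. IR/FoxO1 floxed against IR floxed (fasted) was at 0.00445%, beside 0% for IR/FoxO1 floxed against IR floxed (refed) and 0.534% for FoxO1 dependence (fasted). Both floxed groups as control gave 0.0178% for LIRFKO against IR/FoxO1 floxed (fasted) and 1.38% for LIRFKO against IR/FoxO1 floxed (refed). Without the library labelled IR/FoxO1 floxed fasted, IRF.fl_Fast_523, in any fit the shares were 2.05% for refeeding in IR/FoxO1 floxed, 0.04% for LIRFKO against IR/FoxO1 floxed (fasted), 0.0133% for the refeeding difference of LIRFKO against LIRKO and 0.0356% for the glucose difference of LIRFKO against LIRKO. IR/FoxO1 floxed against IR floxed (fasted) was at 0.00889%, beside 0.138% for IR/FoxO1 floxed against IR floxed (refed) and 0.587% for FoxO1 dependence (fasted). Without the acinar libraries they were 2.12% for glucose in IR floxed, 0.369% for glucose in LIRKO, 0% for LIRFKO against IR/FoxO1 floxed (fasted) and 0.0978% for the refeeding difference of LIRKO against IR floxed. The refeeding difference of LIRFKO against LIRKO was at 0.0133%, beside 0.289% for the glucose difference of LIRKO against IR floxed and 0.133% for IR/FoxO1 floxed against IR floxed (refed). For the last 2 alternatives fewer libraries are the known change, and the cause was not tested further.

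With each mouse left out in turn, the lowest and highest percent of genes changed were 1.86% to 3.52% for refeeding in IR floxed, 1.47% to 2.09% for refeeding in IR/FoxO1 floxed, 0.849% to 1.35% for refeeding in LIRKO and 0.476% to 1.48% for refeeding in LIRFKO. Glucose in IR floxed was at 0.0133% to 1.71%, beside 0.0222% to 2.45% for glucose in LIRKO and 0.0801% to 0.712% for glucose in LIRFKO. For knockouts against their controls and each other they were 4.72% to 7.15% for LIRKO against IR floxed (fasted), 7.61% to 13.2% for LIRKO against IR floxed (refed), 4.04% to 8.62% for LIRKO against IR floxed (glucose) and 0% to 0.04% for LIRFKO against IR/FoxO1 floxed (fasted). LIRFKO against IR/FoxO1 floxed (refed) was at 0.116% to 0.342%. LIRFKO against LIRKO was at 2.27% to 6.62% fasted, 4.74% to 6.66% refed and 2.76% to 6.81% after glucose. For differences of responses, floxed groups and FoxO1 dependence they were 0.0133% to 0.267% for the refeeding difference of LIRKO against IR floxed, 0.00445% to 0.0178% for the refeeding difference of LIRFKO against IR/FoxO1 floxed, 0.00889% to 0.0534% for the refeeding difference of LIRFKO against LIRKO and 0% to 0.213% for the glucose difference of LIRKO against IR floxed. The glucose difference of LIRFKO against LIRKO was at 0.00445% to 0.476%, beside 0% to 0.0801% for IR/FoxO1 floxed against IR floxed (fasted), 0.0311% to 0.116% for IR/FoxO1 floxed against IR floxed (refed) and 0.454% to 1.28% for FoxO1 dependence (fasted). FoxO1 dependence (refed) was at 0.672% to 2.9%. Fewer samples are the known change there, and the cause was not tested.

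Other splits of the same samples into groups of the same sizes were counted, the real one included, and brackets give the real and the highest other count. Chance can be excluded, with 1 of 35 splits as large, for refeeding in IR floxed (811 and 47), refeeding in LIRKO (416 and 19), refeeding in LIRFKO (407 and 93), LIRKO against IR floxed (fasted) (1813 and 693), LIRKO against IR floxed (refed) (2610 and 649), LIRFKO against IR/FoxO1 floxed (refed) (85 and 2), LIRFKO against LIRKO (refed) (1820 and 22) and IR/FoxO1 floxed against IR floxed (refed) (19 and 13). The last count, close to the highest other, was 7 without IRF.fl_Refed_472. Other splits gave as many for glucose in IR floxed (36 and 326, 4 of 35) and IR/FoxO1 floxed against IR floxed (fasted) (8 and 19, 3 of 35), so chance stays open there. The 10 splits of 3 against 3 mice are too few for a share under 0.05. They concern refeeding in IR/FoxO1 floxed (796 and 2) and glucose in LIRKO (134 and 8) and LIRFKO (147 and 1). Others are LIRKO against IR floxed, glucose (1866 and 224), and LIRFKO against LIRKO, fasted (1466 and 12) and glucose (1703 and 5). For LIRFKO against IR/FoxO1 floxed, fasted (1 and 1), 4 of the 10 gave as many. Splits of a difference exchange genotypes within 1 feeding state, or among knockouts and among controls, and so carry the effect common to both sides. They decide nothing about chance, and their high counts point to that structure of the samples. This holds for the refeeding differences of LIRKO against IR floxed (37 and 2334, 5 of 100 splits), LIRFKO against IR/FoxO1 floxed (1 and 115, 12 of 100) and LIRFKO against LIRKO (5 and 1301, 9 of 100). It holds for the glucose differences of LIRKO against IR floxed (0 and 2199, 100 of 100) and LIRFKO against LIRKO (13 and 2967, 13 of 100). It holds for FoxO1 dependence, fasted (210 and 377, 8 of 100) and refed (297 and 939, 3 of 100). For glucose in IR floxed mice the 326 genes of another split, several times the real count, point to a structure of the samples. That split exchanged IR.fl_Fast_486 and IR.fl_GTT_659, acinar libraries, and no cause was tested.

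Signal over background was not available, so the level below which a change is lost was not measured. On simulated data, over genes of any level, 70.1% of changes of 0.5 log2 were recovered in refed LIRKO against IR floxed mice. In the refeeding difference it was 49.3%.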

Other observations

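No test in this part was chosen after its result was seen; the values below describe a sample outside the groups and features outside the named genes.

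Library IRF.KO_GTT_724 has labels that conflict on its treatment, so it belongs to no comparison. It held Insr at 6.51 and Foxo1 at 6.80 log2, against 6.45 to 6.81 and 6.81 to 7.12 in fasted and 6.18 to 6.33 and 6.07 to 6.52 in glucose LIRFKO mice. Gluconeogenesis genes averaged 12.8 in it, where fasted LIRFKO libraries lay between 13.6 and 13.7 and glucose LIRFKO libraries between 12.8 and 13.1. G6pc was at 11.3, against 12.5 to 13.0 fasted and 11.3 to 12.1 after glucose. Heat shock genes lay at 12.1, above the ranges of both the fasted (10.9 to 11.4) and the glucose libraries (11.4 to 11.7). Pancreatic acinar markers were at 7.04 and female-biased liver genes at 7.17, the first above and the second below both ranges (6.06 to 6.19 and 7.59 to 7.99).

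Features without a gene name changed most often between LIRKO and IR floxed mice, with 500 in fasted and 549 in glucose mice beside the refed count. Between LIRFKO and LIRKO they numbered 267 fasted, 471 refed and 456 after glucose. Refeeding changed 100 in IR floxed, 117 in IR/FoxO1 floxed, 27 in LIRKO and 65 in LIRFKO mice.

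Some cell type markers stood high in single libraries. After glucose, the LIRFKO library IRF.KO_GTT_726 held neutrophil markers at 8.40, where the lowest LIRFKO glucose library lay at 6.14, with acute phase genes at 12.72. The fasted IR/FoxO1 floxed library IRF.fl_Fast_533 held acinar markers at 7.47. Between groups, erythroid markers, 4 of them measured and so not tested as a list, had a median of 1.11 in refed IR/FoxO1 floxed against IR floxed mice, and 3 rose adjusted over the list alone.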
